A study of Mus musculus with 18 samples.

How the data were processed

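Striatal polyA RNA of 18 mice was measured by sequencing, with 3 animals in each of 6 groups given by the labels (saline or D-amphetamine on days 1, 7 and 21; injection volume of 10 ml/kg per the labels for amphetamine). One table was analysed, with 29942 gene names in rows and 18 columns whose header numbers match the sample descriptions, and 0 columns of other samples. The deposited values are FPKM, fragments scaled to transcript length and to the number of mapped fragments, as made by the authors. Per the submitters' processing notes, Bowtie and the genome build mm9 were used; versions, the quantifying program and the annotation are not given in the sources used here. The reference in use was of another build, so no coordinates are printed, and it served for gene names, transcript lengths and GC content. Of the tested genes, 11428 matched current symbols and 12899 matched symbols or synonyms. Strand handling is not given, so overlapping and antisense genes cannot be told apart, and members of near-identical families such as haemoglobins and histones are uncertain.

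FPKM are not counts, so no count model was run. Values were tested as log2(FPKM + 1) for 13975 genes with a mean FPKM of at least 1, which understates changes of low genes. limma (version 3.58.1, R version 4.3.3) was fitted to all 18 libraries with 1 mean per group and a mean-variance trend (residual degrees of freedom 12, prior degrees of freedom 2.26), and p values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contrasts were amphetamine minus saline on each day, their mean, the treatment by day interaction and the day effect in saline animals. Of 37 gene lists fixed before the data were examined, covering activity-regulated genes, striatal and other brain cell types, receptors, channels, and metabolic and stress pathways, 36 had at least 3 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over 108 tests, and with an estimated correlation. A mean score per list and library was tested by exact two-sided permutation of treatment within days (8000 assignments). With 3 animals against 3, a single value cannot reach a permutation p under 0.1. Genes were named by a rule fixed in the same way: the 10 largest rises and falls among those past the threshold with separated groups (for the mean, the same direction on the 3 days), or the 5 smallest p where none passed, up to 4 members of a called list and 2 of another, and 14 genes chosen for their role in the striatum.

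Absolute depth was unknown. Low FPKM values of short genes lie on whole-number steps, and 138 of 228 such genes (60.5%) were whole multiples in all libraries within a tolerance of 0.05 reads, which gave relative depth but did not recover reads for nearly all genes. Sums of FPKM ran from 533020 to 682270. Correlations of log2 values between libraries were 0.92 to 0.939 within groups and 0.911 to 0.942 between groups, and no 2 libraries were alike enough to be duplicates.

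Alternatives were a pseudocount of 0.1, no filter and a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, robust moderation, array weights, the replicate number as a block, the range of the label number as a covariate, leaving out each library, and fits to the 6 libraries of a day. Exclusion of 366 short RNA genes, relative depth as a covariate the permutation of list scores, and tests of lists over the mean of days and between days were added after the data were seen. The scripts were tested on simulated data with 200 changed genes among 13975. A log2 change of 1 was recovered for 89% of changed genes on day 1, 89.3% on day 7, 88.4% on day 21, 94% in the mean of days and 77.9% in the interaction. A log2 change of 0.5 was recovered for 55.5%, 58.8%, 60.6%, 85.7% and 26% in the same order. These shares hold for 200 changed genes with independent noise. They do not carry over to a few changed genes, for which the adjustment is stricter. In the data the immediate-early gene Arc, for example, rose by 1.22 on day 1 and did not pass (limma adjusted p = 0.572). A shift of 0.3 planted in the immediate-early list on day 7 was called in 5 of 5 simulations, with 0 false calls in 520 tests of independent genes. Figures were drawn with matplotlib (version 3.10.9).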

Results

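The striatum of both hemispheres, taken dorsal to the anterior commissure, was profiled by sequencing of polyA RNA in 18 sibling mice of the 129Sv/Jae S4 strain. The mice formed 6 groups of 3, which had received intraperitoneal 0.9% saline or D-amphetamine, a psychostimulant that releases dopamine and other monoamines, 7 mg/kg in total per day. Both treatments were sampled on days 1, 7 and 21. The series title ties the study to repetitive behaviours induced by the drug, and the comparisons below address which striatal transcripts differed with amphetamine on each day and across days. Expression was given as FPKM for 29942 gene names, of which 13975 had a mean FPKM of at least 1 and were tested. The total number of reads per library was unknown. Relative depth, read from the steps between low values, ran from 0.652 to 1 of the deepest library, and averaged 0.811 against 0.884 on day 1, 0.822 against 0.894 on day 7 and 0.765 against 0.873 on day 21 in the amphetamine and saline groups. The labels describe 3 mice per group, so the spread given here is between animals.

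Averaged over the 3 days, amphetamine raised a set of activity-regulated transcripts. Fos, a subunit of the AP-1 transcription factor, was 1.98 ± 0.16 (SE) higher on the log2 scale (limma adjusted p = 4.91e-05), and Btg2, an antiproliferative immediate-early gene, was 1.58 ± 0.12 higher (limma adjusted p = 2.74e-05). The transcription factor genes Egr2, Junb, Npas4 and Nr4a1 rose by 1.48, 1.26, 1.02 and 0.86 on the same scale. Arc, which encodes a regulator of the synaptic cytoskeleton and of glutamate receptor traffic, rose by 1.35. Dusp1 and Dusp6, phosphatases that act on MAP kinases, rose by 1.15 and 0.76. In all, 17 genes passed the threshold in limma and all 17 were higher with amphetamine. Among them 13 belonged to the fixed list of immediate-early genes and 3 to the list of feedback regulators of ERK signalling. Rgs2, a regulator of G protein signalling, Cyr61, a secreted matrix-associated protein, and Egr1, another zinc finger transcription factor, rose by 0.36, 0.42 and 0.66. Ppp1r15a, Fosb, Sik1 and Plk2, named after their values were seen, completed the set together with AK006051, a transcript without a matching gene symbol that rose by 1.30. Btg2, Fos, AK006051 and Dusp1 passed the threshold under each of 29 alternative settings, whereas Nr4a1 did so under 8, Egr1 under 9 and Dusp6 under 15. With the replicate number as a block 5 genes passed, 4 of them among the 17. With relative depth as a covariate 9 passed, and with array weights 28. The count was 8 without saline replicate 1 of day 7, 9 without saline replicate 3 or amphetamine replicates 2 or 3 of day 7 or amphetamine replicate 1 of day 21, 10 without saline replicates 2 or 3 of day 1, and 11 without amphetamine replicate 1 of day 7 or saline replicates 1 or 3 of day 21.

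The same genes were described as groups. Of 43 tested immediate-early genes, 39 were higher with amphetamine over the 3 days, 13 rose over all genes tested and 28 rose when adjusted over the list alone. The list was called by limma's camera (adjusted p = 1.86e-44) and remained so with an estimated correlation (adjusted p = 0.00692 with an estimated correlation). Its mean level lay higher in every amphetamine library than in every saline library of the same day. An exact permutation of treatment within days gave p = 0.00025 (adjusted p = 0.0045 over 36 lists). That is the smallest p possible when animals are assigned freely within days, without pairs. Of 15 ERK feedback genes, which share Dusp1 with the former list, 12 were higher, 3 rose over all genes and 7 rose when adjusted over the list alone, among them the Sprouty genes Spry1 and Spry2, named after their values were seen. That list was also called (camera adjusted p = 6.44e-12, adjusted p = 0.0231 with an estimated correlation), and its exact permutation p was likewise 0.00025 (adjusted p = 0.0045). Of 13 neuropeptide genes 12 were higher, none passed over all genes and 1, Pdyn, rose when adjusted over the list alone. The neuropeptide list was called by camera (adjusted p = 0.000111, adjusted p = 0.03 with an estimated correlation), whereas its exact permutation p of 0.0215 did not hold after adjustment (adjusted p = 0.189). The 3 tested choroid plexus genes, markers of a neighbouring tissue, were the remaining list called with an estimated correlation, out of 19 lists called over the 3 days at the preset correlation, with a median log2 difference of 0.32 (camera adjusted p = 0.000193, adjusted p = 0.0231 with an estimated correlation), 2 rising when adjusted over the list alone, none over all genes, and an exact permutation p of 0.0535 (adjusted p = 0.241). These tests over the mean of the 3 days were chosen after the data were seen.

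**Figure D1:**
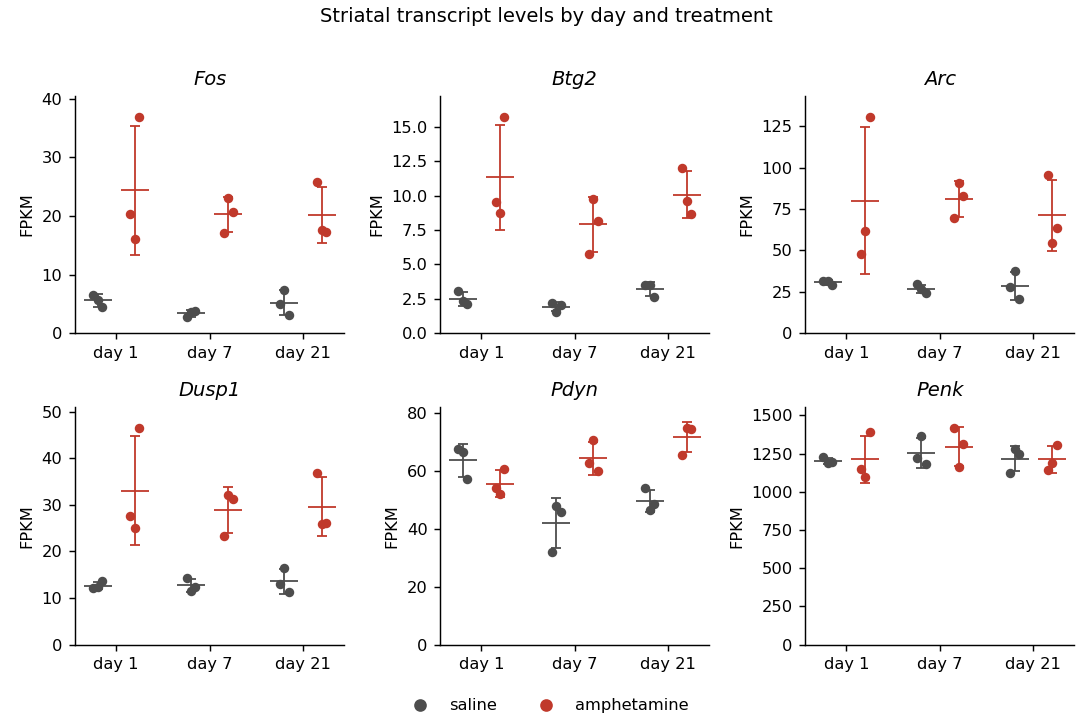
FPKM of 6 genes in each library, by day (horizontal axis) and treatment (colour), with group means and SD bars (n = 3); each vertical axis starts at 0. Fos, Btg2, Arc and Dusp1 lay higher in every amphetamine library than in every saline library of the same day, Pdyn did so on days 7 and 21, and Penk overlapped on each day.

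On day 1, Btg2 was the single gene past the threshold. Its FPKM was 2.498 ± 0.488 (SD, n = 3) with saline and 11.3 ± 3.80 (SD, n = 3) with amphetamine, a log2 difference of 1.78 ± 0.21 (SE; limma adjusted p = 0.00665). Fos was 5.61 ± 1.07 with saline and 24.38 ± 10.97 with amphetamine and missed the threshold (limma adjusted p = 0.0525), as did AK006051 (limma adjusted p = 0.0525). One amphetamine animal, replicate 3, had the highest Fos, Btg2 and Arc values of that group, with Fos at 36.8 against 20.2 and 16.1 in the other two. Without short RNA genes, a filter chosen after the data were seen, 4 genes passed on day 1, while leaving out amphetamine replicate 2 gave 8, saline replicates 1 and 3 gave 3 each and saline replicate 2 gave 2. Btg2 did not pass in a fit to the 6 libraries of day 1 (limma adjusted p = 0.643), and no gene passed with the replicate number as a block. In the main fit 1013 genes had an unadjusted p under 0.05 in limma on day 1, where 699 would arise by chance. The numbers were 687 on day 7 and 749 over the mean of days. Genes are correlated and the median over all tested genes was 0.0469 on day 1, so the excess does not count responding genes.

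On day 7, Fos, Btg2 and AK006051 rose. Fos went from 3.43 ± 0.60 FPKM (SD, n = 3) with saline to 20.3 ± 3.03 (SD, n = 3) with amphetamine, a log2 difference of 2.26 ± 0.28 (SE; limma adjusted p = 0.014). Btg2 was 1.94 ± 0.35 against 7.91 ± 2.01 FPKM (limma adjusted p = 0.014) and AK006051 4.17 ± 0.66 against 12.1 ± 1.92 FPKM (limma adjusted p = 0.0349). Npas4, an activity-dependent transcription factor, stood at 3.25 and 12.4 FPKM and fell just outside (limma adjusted p = 0.0615). The count was 0 when any of 5 of the 6 libraries of that day was left out, the exception being amphetamine replicate 1. It was also 0 with the replicate number as a block. A fit to the 6 libraries of that day kept Fos (limma adjusted p = 0.0191) but not Btg2 or AK006051 (limma adjusted p = 0.191 and 0.169).

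On day 21 no gene passed the threshold in limma, with 768 at an unadjusted p under 0.05 where 699 would arise by chance. The 5 genes with the smallest p were BC116340, Btg2, Fos, AK006051 and Dusp1. Fos stood at 5.18 ± 2.14 FPKM with saline and 20.2 ± 4.77 with amphetamine, and Btg2 at 3.21 ± 0.49 and 10.1 ± 1.72 (SD, n = 3 in each group), with limma adjusted p values of 0.0717 and 0.0604. BC116340 had FPKM values of 12.3, 20.1 and 17.2 with saline, and with amphetamine 3.10 in replicate 2 while it was listed at 0 in replicates 1 and 3. Restricting the test to genes with a mean FPKM of at least 5 gave 4 genes past the threshold on that day, and leaving out saline replicates 2 or 3 or amphetamine replicate 3 gave 1 each and amphetamine replicate 2 gave 2.

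Within single days, camera called 29 of 108 combinations of list and day, 20 upward and 9 downward, whereas none was called with an estimated correlation. Random divisions of the libraries within days gave a median of 20 such calls, so the calls outside the activity-regulated lists are given here as values. By limma's fry, an alternative list test, immediate-early genes were called on days 1 and 7 (fry adjusted p = 0.0325 for both). ERK feedback genes on day 7 and choroid plexus genes on day 1 were called likewise (fry adjusted p = 0.0325 for both), as were neuropeptides on day 7 (fry adjusted p = 0.0426). Immediate-early genes were higher on days 1, 7 and 21, with 38, 39 and 37 of 43 members higher (adjusted p = 0.206, adjusted p = 0.108 and adjusted p = 0.108 with an estimated correlation). Adjusted over the list alone, 17, 22 and 16 members rose, against 1, 2 and none over all genes. ERK feedback genes were higher in 12, 13 and 11 of 15 members (adjusted p = 0.568, adjusted p = 0.108 and adjusted p = 0.546 with an estimated correlation), with 2, 7 and 4 rising when adjusted over the list alone and none over all genes.

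Pdyn, which encodes the precursor of the dynorphin opioid peptides, had FPKM means of 63.7 ± 5.64 with saline and 55.6 ± 4.59 with amphetamine on day 1, 41.9 ± 8.58 and 64.4 ± 5.67 on day 7, and 49.7 ± 3.86 and 71.6 ± 5.21 on day 21 (SD, n = 3). It did not pass over all genes on day 7 (limma adjusted p = 0.237) or day 21 (limma adjusted p = 0.769), and rose on both days when adjusted over the neuropeptide list alone (adjusted p = 0.00286 and 0.0148). The neuropeptide list was called on those days, with median log2 differences of 0.29 and 0.11 (adjusted p = 0.108 and adjusted p = 0.203 with an estimated correlation). Tac1, the substance P precursor of direct-pathway neurons, stood at 219 ± 9.81 FPKM with saline and 270.0 ± 21.5 with amphetamine on day 21 (limma adjusted p = 0.869). Penk, the enkephalin precursor, differed by 0.01 ± 0.06 (SE) on the log2 scale over the 3 days, Drd2, the dopamine D2 receptor, by −0.08 ± 0.07 and Drd1a, the D1 receptor, by −0.10 ± 0.04, none past the threshold (limma adjusted p = 0.999, 0.999 and 0.784). On day 7 Drd1a (−0.19) and Eya1 (−0.37), a transcriptional coactivator and direct-pathway marker, fell and Pdyn rose when adjusted over the direct-pathway list alone (adjusted p = 0.0378, 0.0378 and 0.0022), none over all genes, and the list was not called on that day (camera adjusted p = 0.877). The synaptic scaffold gene Homer1 (−0.06), the guanine nucleotide exchange factor genes Rasgrp1 (−0.10) and Rasgrp2 (−0.05), the mu-opioid receptor gene Oprm1 (0.13) and the glucocorticoid-responsive Fkbp5 (0.14) did not pass either (limma adjusted p = 0.999, 0.865, 0.999, 0.999 and 0.844).

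**Figure D2:**
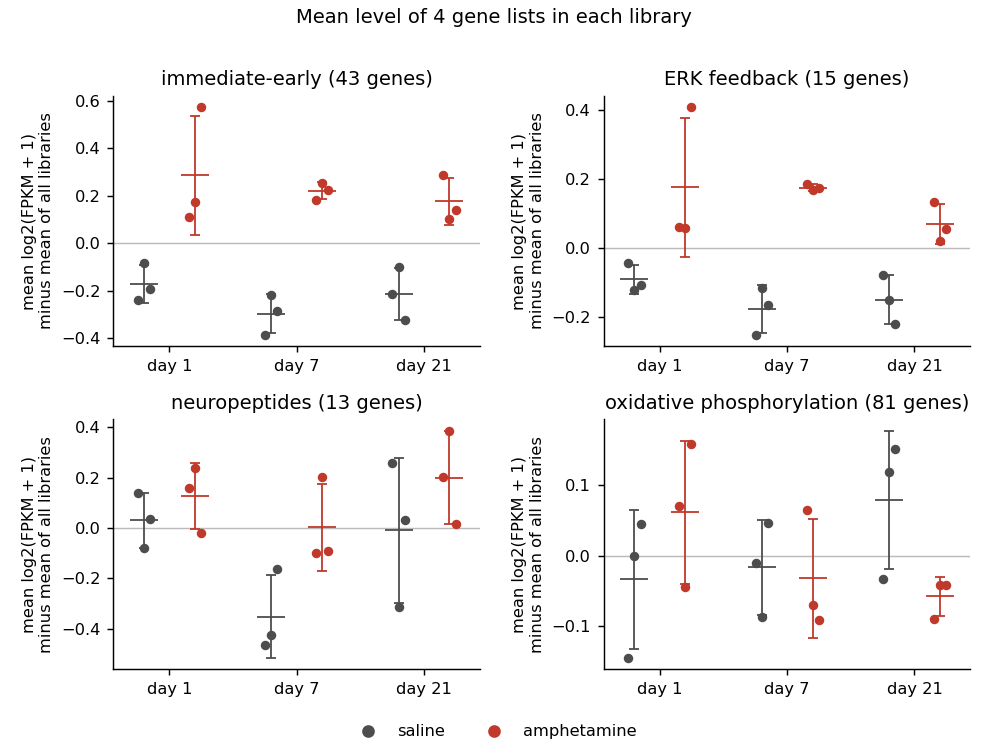
Mean log2(FPKM + 1) of the members of 4 lists in each library, relative to the mean of all 18 libraries (vertical axis), by day and treatment, with group means and SD bars (n = 3). The immediate-early and ERK feedback scores lay higher in every amphetamine library than in every saline library of the same day, while the neuropeptide scores overlapped on days 1 and 21 and the oxidative phosphorylation scores on days 1 and 7.

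Other lists called by camera within a day, none of which held with an estimated correlation, had smaller median log2 differences in most cases. The median over all tested genes was 0.0469 on day 1, 0.0036 on day 7 and −0.0201 on day 21. Camera compares a list with the other genes, so a list with a median near 0 could be called lower on day 1. The dehydrogenase and oxidase gene Xdh and the clock gene Per1, both of the glucocorticoid response list, rose by 0.73 and 0.42 on day 7 when adjusted over the list alone, where 2 of 20 members passed, and none passed over all genes. That list had medians of 0.25 on day 1 and 0.15 on day 7 (adjusted p = 0.788 and adjusted p = 0.654 with an estimated correlation). Unfolded protein response genes had medians of 0.15 and 0.11 on days 1 and 7 (adjusted p = 0.733 and adjusted p = 0.654 with an estimated correlation). Oxidative phosphorylation genes had medians of 0.11 on day 1, with 71 of 81 higher, and −0.12 on day 21, with 76 of 81 lower (adjusted p = 0.788 and adjusted p = 0.654 with an estimated correlation). The day 1 median was 0.051 without amphetamine replicate 3 and 0.053 without saline replicate 1 of that day. Cytosolic ribosomal protein and heat shock genes had medians of −0.10 and −0.09 on day 21 (adjusted p = 0.788 for both with an estimated correlation). Markers of direct-pathway projection neurons had medians of −0.04 on day 1 and 0.12 on day 21, and late-response and circadian clock genes 0.13 and 0.06 on day 7 (adjusted p = 0.568 for each with an estimated correlation). Glutamate receptor and postsynaptic genes and potassium channels had medians of −0.02 and 0 on day 1, where the mean of the channels was −0.02, and septal and pallidal markers 0.05 on day 21 (adjusted p = 0.568 for each with an estimated correlation). Histone genes had a median of −0.01 on day 1 (adjusted p = 0.838 with an estimated correlation). General projection neuron markers and ependymal markers had medians of −0.09 and 0.47 on day 7 (adjusted p = 0.771 and adjusted p = 0.654 with an estimated correlation).

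Markers of neighbouring structures varied between libraries. Of the choroid plexus list 3 genes were tested, and on day 1 Ttr, the transthyretin carrier made in that tissue, stood at 12.9, 8.64 and 2.47 FPKM with saline and 91.1, 18.1 and 42.9 with amphetamine, and Kl was 0.52 ± 0.12 (SE) higher on the log2 scale (limma adjusted p = 0.471 over all genes, 0.00195 adjusted over the list alone). The list was called on day 1 (camera adjusted p = 0.00414, adjusted p = 0.152 with an estimated correlation). Haemoglobin transcripts were uneven between animals, with Hbb-b1 at 29.4, 199.3 and 99.2 FPKM with saline and 34.7, 31.4 and 81.5 with amphetamine on day 7. The blood list was called lower on day 7 and higher on day 21 (adjusted p = 0.568 and adjusted p = 0.689 with an estimated correlation). Over the 3 days the medians of the astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural lists lay between 0.02 and 0.09 on the log2 scale, means of days that differed in sign for some of them. Of these 6, the precursor list was called by camera over the 3 days (7 of 8 higher, adjusted p = 0.049, adjusted p = 0.51 with an estimated correlation). On day 1 the medians were 0.24 for oligodendrocyte markers (16 of 16 higher), 0.18 for astrocyte markers (13 of 15) and 0.17 for oligodendrocyte precursor markers (7 of 8), none called by camera (adjusted p = 0.0502, 0.0815 and 0.181), and oligodendrocyte markers stood at −0.07 on day 7 and −0.14 on day 21. Over the 3 days the medians of the choroid plexus and ependymal lists were 0.32 and 0.26, with 3 of 3 and 7 of 7 members higher. The ependymal list was called by camera over the 3 days (adjusted p = 0.00966, adjusted p = 0.469 with an estimated correlation). Cortical glutamatergic markers were lower in 9 of 10 members (median −0.14, camera adjusted p = 0.00514, adjusted p = 0.343 with an estimated correlation), and septal and pallidal markers higher in 10 of 12 (median 0.10, camera adjusted p = 0.0215, adjusted p = 0.338 with an estimated correlation). Slc17a7, a vesicular glutamate transporter gene of cortical neurons, ran from 1.29 to 48.4 FPKM between libraries. On day 21 the choroid plexus and ependymal medians were 0.195 (2 of 3 higher) and 0.006 (4 of 7 higher), and their means 0.007 and −0.015.

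Whether the response to amphetamine differed between days was tested directly. No gene passed the interaction test in limma, with 873 at an unadjusted p under 0.05 where 699 would arise by chance and a smallest adjusted p of 0.652. Pdyn had an unadjusted interaction p of 0.000835 in limma (adjusted p = 0.669) and Npas4 of 0.0348 (adjusted p = 0.773). For Fos, Btg2, Arc and Dusp1 the unadjusted interaction p was 0.502, 0.423, 0.715 and 0.778 in limma. Across the 43 immediate-early genes the log2 differences of 2 days correlated with r = 0.856 for days 1 and 7, 0.9 for days 1 and 21 and 0.873 for days 7 and 21, against 0.064, 0.045 and −0.054 across all tested genes. These are correlations across genes, which are not independent replicates, and no library was shared between days.

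Among saline animals, 1 gene differed between days, Cd72, a B cell surface receptor, with FPKM means of 1.08 ± 0.32, 3.29 ± 0.22 and 2.61 ± 0.41 on days 1, 7 and 21 (SD, n = 3; limma adjusted p = 0.0318). With the range of the label number as a covariate 15 genes passed. All day 1 libraries except saline replicate 1 fall in a range that holds no other day. That fit therefore sets day 1 saline against the other days through that library alone. The count was 0 with no filter, under quantile normalization and with relative depth as a covariate. It was 0 without saline replicates 2 or 3 of day 7 or saline replicate 2 of day 21, and 2 without saline replicates 1 or 3 of day 1 or saline replicate 3 of day 21. Of 100 random assignments of day within the saline libraries, the real one included, 23 gave as many.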

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

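The tests of the FPKM scaling, of non-neuronal cells on single days, of choroid plexus and ependymal tissue and of prodynorphin, and the list tests of differences between days, were chosen after the results were seen. Several lists differed between days in their response to amphetamine by camera at the preset correlation, each with an adjusted p of 0.978 with an estimated correlation. As medians over genes of the difference between the log2 responses of 2 days, oxidative phosphorylation genes stood at −0.114 for day 7 against day 1, −0.232 for day 21 against day 1 and −0.124 for day 21 against day 7. Heat shock genes differed by −0.202 for day 21 against day 1 and −0.124 for day 21 against day 7, and unfolded protein response genes by −0.21 and −0.157 for the same pairs. Neuropeptides differed by 0.167 and oligodendrocyte markers by −0.339 for day 7 against day 1, direct-pathway neuron markers by 0.219 for day 21 against day 1, and blood markers by 1.388 for day 21 against day 7.

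Immediate-early genes were higher with amphetamine on the 3 days, with a median log2 difference of 0.313. The median was 0.319 ± 0.071 with relative depth as a covariate and 0.306 ± 0.057 after median-of-ratios scaling. These values argue against depth and scaling as the cause. Here and in the next paragraph, ± after a list median is the standard error of the list's mean score over libraries, not of the median. The highest median among 6 non-neuronal lists was 0.085 ± 0.072 over the 3 days, in oligodendrocyte precursor markers. Oligodendrocyte markers had a wider spread, at 0.026 ± 0.136. All 6 lay below 0.313 by more than their standard errors, which argues against such cells as the whole cause over the 3 days. On day 7 the highest median was 0.065 ± 0.066, in microglial markers, against 0.29 for immediate-early genes. This argues against microglia there, but the spread of the other lists was not weighed on that day. On day 21 the highest was 0.09 ± 0.125, which leaves that day open. On day 1 oligodendrocyte markers reached 0.241, but with astrocyte, oligodendrocyte and precursor scores as covariates the day 1 immediate-early median was 0.339 ± 0.118 against 0.323 without them. Choroid plexus and ependymal markers, outside those 6, were higher by medians of 0.318 and 0.263 over the 3 days, but with their scores as covariates the immediate-early median was 0.364 ± 0.080, which argues against such tissue as the cause. Choroid plexus and ependymal scores were tried as covariates only over the mean of days, although their day 1 medians were 0.519 and 0.36. A candidate explanation for days 1 and 7 is a transcriptional response of striatal cells to the drug. It was not tested and stays a hypothesis. The interval between injection and dissection is not given in the sources used here.

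Prodynorphin was higher with amphetamine on days 7 and 21 but not on day 1, with differences of differences against day 1 of 0.82 ± 0.18 (SE) for day 7 and 0.71 ± 0.18 for day 21. For day 7, 74.5 ± 16.5% came from the saline groups, which were lower on day 7 than on day 1 by 0.61 ± 0.13 (limma unadjusted p = 0.00028), while the amphetamine groups differed by 0.21 (limma unadjusted p = 0.124). For day 21 the saline share was 49.4 ± 19%, with saline at −0.35 (limma unadjusted p = 0.0155) and amphetamine at 0.36 (limma unadjusted p = 0.0135), which leaves open which groups it rests on. After these shares, ± is the standard error of the saline difference alone, divided by the difference of differences taken as fixed. It leaves out the error of the latter. Other direct-pathway members had medians of −0.028 ± 0.078 for day 7 and 0.206 ± 0.078 for day 21, and other striosomal members −0.044 ± 0.091 and −0.139 ± 0.091 (−0.035 ± 0.071 and −0.05 ± 0.071 for both lists together), each under 0.5 of the prodynorphin difference, which argues against the share of such tissue as the main cause but leaves a smaller direct-pathway part on day 21 open. Most of the day 7 difference thus lay in the saline values. This split cannot tell a shifted baseline from an effect of the drug, because the saline group is also the control of the same day. Effects of age, repeated injection or litter on the saline values were not tested.

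Oxidative phosphorylation genes were higher with amphetamine on day 1 and lower on day 21, with medians of 0.106 and −0.125. The medians over all tested genes were 0.0469 and −0.0201 on those days. The difference between these days in the list median kept 91.1 ± 6.3% of its size after a fit on transcript length and GC content. With relative depth as a covariate it kept 105.9 ± 3.2%. Here ± is the SD over resamplings of the 81 genes, which are correlated (estimated correlation 0.413), so it does not measure the spread between animals. As point values they argue against these as the whole cause. Left open is a single library: without amphetamine replicate 3 of day 1 the difference kept 73.4%, and without saline replicate 1 of that day 76.8%, while the day 1 median itself went from 0.106 to 0.051 and 0.053. No biological explanation was tested beyond the groups themselves, and the list had an adjusted p of 0.788 on day 1 and 0.654 on day 21 with an estimated correlation.

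Other divisions of the libraries were compared with the real one. For the mean of 3 days, 2 of 100 random divisions within days, the real one included, gave as many as 17 genes. A count of 17 was therefore seldom reached by chance. However, 33 of the 99 other divisions gave at least 1 gene, so a single call near the threshold is weak evidence. The highest other gave 44 genes, none shared with the real calls. Whether that division reflects a structure of the samples or chance was not tested. Relative depth averaged 0.797 in that set against 0.886 in the rest, a gap in the same direction as that between amphetamine and saline libraries. For the lists, 3 of 100 gave as many as 29 calls, with a highest other of 31 and a median of 20. For the saline day effect 23 of 100 gave as many as 1 gene, with a highest other of 2, so chance could not be excluded. For the interaction the real count was 0, which 100 of 100 reach by construction (highest other 3), so that comparison says nothing about chance. The 10 divisions of 3 against 3 within a day are too few for a share under 0.05: on day 1, 4 of 10 gave as many as 1 gene (highest other 2), on day 7, 1 of 10 gave as many as 3 (highest other 1), and on day 21, 10 of 10 gave as many as 0, again by construction (highest other 1).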

How the results depend on the processing

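The exclusion of short RNA genes and the depth covariate were chosen after the data were seen. Among the genes followed over the mean of days, which included 11 of the 17 past the threshold, Penk alone changed sign, to −0.009 with array weights, and ran from −0.021 to 0.039 when 1 library was left out (negative at −0.021, −0.008, −0.005, −0.005 and −0.001). The count over the mean of days was 28 with array weights, 11 with the label-number covariate and 9 with the depth covariate. On day 1 it was 3 with a filter of 5 FPKM, 2 with robust moderation, 4 with array weights, 4 with the label-number covariate, 3 with the 6 libraries of the day (Mir345, Mir138-1 and Snora23, all short RNA genes, with Btg2 lost) and 4 without short RNA genes. On day 7 it was 5 with the filter of 5, 6 with array weights and 9 with the 6 libraries of the day, of which Fos alone was shared, Btg2 and AK006051 were lost, and Mir677, Mir384, Snora5c and Snord1b were short RNA genes. On day 21 it was 4 with the filter of 5, 3 with quantile normalization, 5 with array weights, 6 with the 6 libraries of the day, all 6 of them short RNA genes, and 4 without short RNA genes. The saline day effect gave 0 with no filter, with the filter of 5, which removes Cd72 before testing, with quantile normalization and with the depth covariate. It gave 3 with array weights and 15 with the label-number covariate, with which the interaction gave 2. Day 1 libraries except saline replicate 1 form a label range of their own, so the count of 15 rests on that library for day 1. List calls numbered 0 with an estimated correlation and 5 with fry. The causes were not tested. With the replicate number as a block the counts were 0 on day 1, 0 on day 7 and 5 over the mean of days. The block cost residual degrees of freedom. No label says whether the replicate numbers pair the animals. In the sample descriptions, same-numbered saline and amphetamine libraries of a day mostly carry neighbouring numbers, except replicate 1 of day 1. Such an order would go with pairing, which the main fit and the permutation within days do not take into account. Same-numbered libraries correlated in their deviations at −0.085 to 0.145. On day 21 each correlated best with its own number (0.114, 0.043 and 0.145). With 3 animals per group these values cannot settle whether the animals were paired. Leaving out 1 library gave 1 to 8 genes on day 1, 0 to 2 on day 7, 0 to 2 on day 21, 8 to 17 over the mean of days, 0 to 2 for the interaction, 0 to 2 for the saline day effect and 20 to 33 list calls. Over the mean of days it was 8 without saline replicate 1 of day 7 and 9 without amphetamine replicate 1 of day 21. Relative depth differed by 1.535-fold between libraries and absolute depth was unknown.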

Other observations

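The list of circadian clock genes also held transcripts that were higher with amphetamine. Over the 3 days Bhlhe40, a transcriptional repressor of the clock, was 0.38 ± 0.07 (SE) higher on the log2 scale, Gm129 0.48 ± 0.11, Per2 0.31 ± 0.09 and Per1 0.25 ± 0.07, and 4 of 20 members rose when adjusted over the list alone and none over all genes (limma adjusted p = 0.0907 for Bhlhe40 over all genes). The list had an adjusted p of 0.469 with an estimated correlation and an exact permutation p of 0.0262 (adjusted p = 0.189). Among late-response genes Gpr3, Vgf and Scg2 were higher by 0.61, 0.37 and 0.29 and Acvr1c and Rgs4 at −0.18 and −0.19, each past the threshold when adjusted over the list alone, and Rgs2 passed over all genes as well. These members were named after their values were seen (adjusted p = 0.338 for the list with an estimated correlation).

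One hypothesis was that genes outside the activity-regulated lists responded alike on separate days while each stayed below the threshold. It was tested on genes with an unadjusted p under 0.01 on the earlier day, as the share with the same sign on the later day, against 20 relabellings of the later day's libraries. From day 1 to day 7 the share was 51.4% of 185 genes, reached by 10 of 20 relabellings, and from day 1 to day 21 it was 38.9%, reached by 19 of 20, so no shared response was seen. From day 7 to day 21 it was 70.3% of 138 genes, reached by 2 of 20 relabellings with a highest other of 73.2%. By the rule set beforehand, a share reached by 2 of 20 relabellings counts against the hypothesis. Because 20 relabellings cannot resolve a share under 0.05, a response shared by days 7 and 21 was neither shown nor excluded.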
